A study of Equus asinus with 3 samples.

How the data were processed

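Single-cell RNA sequencing was analysed for 3 donkey (Equus asinus) libraries, 1 each from testis, the caput (head) of the epididymis and the corpus (body) of the epididymis. Per the series design, the tissue came from 3 sexually mature males; how the animals relate to the libraries is not given in the sources used here, so each group counted as 1 sample. Per the labels' protocols, tissue was kept in storage solution for up to 48 h and digested for 15 min at 37 C with collagenase IV and DNase I. It was then strained and loaded on DNBelab C4 droplets, in which each transcript molecule carries a unique molecular identifier (UMI). The labels give the cell type as germ cells for testis and as somatic cells for both epididymal libraries, and no sort is described. The cauda epididymis, which the protocol also names, was not analysed here.

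The deposited matrices hold UMI counts, whole numbers that are not normalized, for 32159 features in testis, 33722 in caput and 32140 in corpus (34267 in all, with a feature absent from a file taken as 0), and were written by PISA v0.12, per the file headers. The submitters' processing notes also name Cell Ranger 2.1.1, without its role. The aligner and genome build are not given in the sources used here. The deposited barcodes had a floor of UMIs that differed between libraries, at 1816 in testis, 843 in caput and 298 in corpus, and per the barcode names some cells were merged from more than 1 bead (1266, 478 and 363 barcodes). Gene symbols were those of the files, and a RefSeq gene table, used for names only, gave symbols to 749 of 18266 features with a locus identifier. All 88 genes of a list of X-linked genes were placed on X by that table. No mitochondrially encoded gene was among the features (0), so the planned maximum of 20% mitochondrial UMIs could not be applied.

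Cells with at least 200 genes were kept. Doublets were scored per library in the manner of Scrublet, with 2 simulated doublets per cell and a threshold at the minimum between the peaks of the simulated scores (scikit-image 0.26.0). This marked 112 barcodes in testis (1.30%), 2 in caput (0.0211%) and 0 in corpus, so in both epididymal libraries doublet calling did not work and doublets remain. The filters left 8498 of 8610 barcodes in testis, 9476 of 9478 in caput and 9609 of 9611 in corpus. Each library was clustered on its own, on the logarithm of counts per 10000 with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, seed 0), which gave 16, 13 and 9 clusters. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

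Markers, gene lists, comparisons and the rule for named genes were fixed before the data were examined. The thresholds by which markers name a cluster were set after the clusters were seen. A marker counted in a cluster when it was at least 2-fold above the median of the other clusters (with 10 CPM added), in at least 5% of cells and with at least 5 UMIs. A name needed at least 3 markers, 20% of those measured and a mean log2 ratio of 0.6. A cluster stayed unnamed where its markers averaged under 2-fold (on a log scale) and a list of very long genes took a large share of UMIs. Large was at least 1.5 times the share in the library's median cluster. With markers above that average, testis clusters 14 and 15 (0.415% and 0.372%) and corpus clusters 3 and 4 (2.75% and 3.14%) kept a name despite such a share. Clusters also stayed unnamed where the markers of another lineage stood at 0.6 or more of their level in that lineage's own clusters, or where at least 5 of the 10 leading genes were cell-cycle genes. A class compared between libraries needed at least 50 cells in each.

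With 1 library per group no p-value was computed and no difference has a replicate check. Counts were summed per library and class and given as CPM (UMIs scaled so that each sum has 1e6), with exact Poisson intervals; shares have Clopper-Pearson intervals and ratios exact conditional binomial intervals. All intervals are at 95% and cover counting error only. A gene was listed as higher on one side when the whole interval of its ratio lay beyond 4-fold and that side had at least 50 UMIs. A ratio against 0 UMIs is given as a lower bound, set against a floor of 3 counts over the group. For a gene list, members with at least 50 UMIs on the higher side were counted by whether the whole interval lay beyond 2-fold, and the median log2 ratio (0.5 counts added) of members with a mean of at least 50 CPM was placed among 10000 random lists of the same size matched on expression, as a description of these libraries. Named genes were, in each direction, the 12 genes with a symbol whose interval lay farthest from 1 (5 in classes other than luminal epithelial), up to 4 members per list with the largest ratio, and, along the germ stages, the up to 4 members per list with the most UMIs; X-linked, hormone receptor and steroidogenesis genes had no such limit.

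The size rule was tested on simulated counts with 200 changed genes. Both sides were drawn from the same profile with counting error only. The changed genes were picked among those with at least 20 UMIs expected in the corpus sum before the change. Of genes changed 8-fold it listed 85.0% in the luminal comparison (29452 genes run), 74.5% in the fibroblast comparison (28345) and 97.0% in whole libraries (33592). Of genes changed 2-fold it listed 0 in each, and it listed 0 unchanged genes. These shares hold for genes of that depth only. The absence of unchanged genes sets no limit on differences between animals or libraries, which were not simulated. Alternatives changed the gene minimum, doublet treatment, clustering, scaling (with TMM factors from edgeR 4.0.16, or totals without the 20 most abundant genes), the UMI minimum and the weighting of cells. The log2 ratio of the TMM factors, caput over corpus, was -0.19 in luminal cells, -0.17 in whole libraries and -0.28 in T or NK cells. For testis over caput fibroblasts it was 0.22, for testis over corpus fibroblasts 0.32, and elsewhere less than 0.1 in size. The log2 ratios of all genes moved by the same amounts in the opposite direction. Further alternatives were chosen after seeing the data.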

Results

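Transcriptomes of single cells were collected from 3 donkey tissues along the path of the sperm, the testis, in which sperm are made, and the caput and corpus of the epididymis, the duct in which they mature. There was 1 library per tissue and no replicate. The testis library held 47686179 UMIs in 8610 barcodes, the caput library 13203203 in 9478 and the corpus library 4142512 in 9611. Kept cells had a median of 4676 UMIs and 2354.5 genes in testis, 1145 UMIs and 799 genes in caput, and 371 UMIs and 321 genes in corpus. This gap in depth stands beside every share of cells given here.

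To see which cells each tissue contributed, clusters were named from fixed markers. Germ-like cells made up 90.3% of testis cells (95% interval 89.6 to 90.9%, 7670 of 8498). Among them, 449 late spermatocyte-like cells (5.85%), 1905 round spermatid-like cells (24.8%) and 553 elongating spermatid-like cells (7.21%) could be named, and 62.1% lay in germ-like clusters that kept no name, among them cluster 13 (56 cells), which mixed markers of elongating spermatids and late spermatocytes. These names depend on the clustering: spermatids, 32.0% of germ-like cells here, took 47.9% with a larger set of variable genes and 0% with the libraries clustered together, where clusters of several germ stages took their place. Round spermatid-like cells include testis cluster 6 (713 cells), whose 10 leading genes hold 0 round spermatid markers and 1 elongating spermatid marker, TSSK2. No cluster was named for spermatogonia or early spermatocytes, which sets no limit on such cells in the unnamed clusters. Testis somatic cells were few, with 55 fibroblast-like cells (0.647%) and 31 T or NK-like cells (0.365%), the latter led in part by the stress genes FOS, JUN and HSPA6. Testis clusters of mixed lineages held 4.59%. No Sertoli-like or Leydig-like cluster met the rule for a name.

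The caput library held 2875 luminal epithelial-like cells (30.3%, 29.4 to 31.3%), the cells that line the duct and secrete into it. It also held 96 clear or narrow cell-like cells (1.013%), 849 T or NK-like (8.96%), 715 fibroblast-like (7.55%), 499 macrophage-like (5.27%) and 19 endothelial-like cells (0.201%). Germ-like clusters added 313 cells, 217 of several stages and 96 elongating spermatid-like. In corpus there were 2970 fibroblast-like cells (30.9%), 866 T or NK-like (9.01%), 645 macrophage-like (6.71%), 164 luminal epithelial-like (1.71%, 1.46 to 1.99%) and 79 endothelial-like cells (0.822%). The luminal share in corpus was 7.25% with a minimum of 500 genes and 1.09% without the 5% highest doublet scores. Outside clusters led by very long genes it was 3.38%, and that of caput 53.2%. Clusters led by very long genes such as PEX5L, DCLK1, GRIN2B and PTPRD stayed unnamed, and held 4.14% of testis, 43.0% of caput and 49.5% of corpus cells. The largest of those in caput, cluster 0 (2517 cells), matched 6 of 16 endothelial markers, and with the libraries clustered together 3391 caput cells lay in a cluster named endothelial. A caput cluster led by cell-cycle genes (0.422%) and a mixed corpus cluster (1.32%) stayed unnamed as well. Shares of classes between libraries are not compared, because the genes that define the clusters differ between the tissues and cell depth does too.

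**Figure D1:**
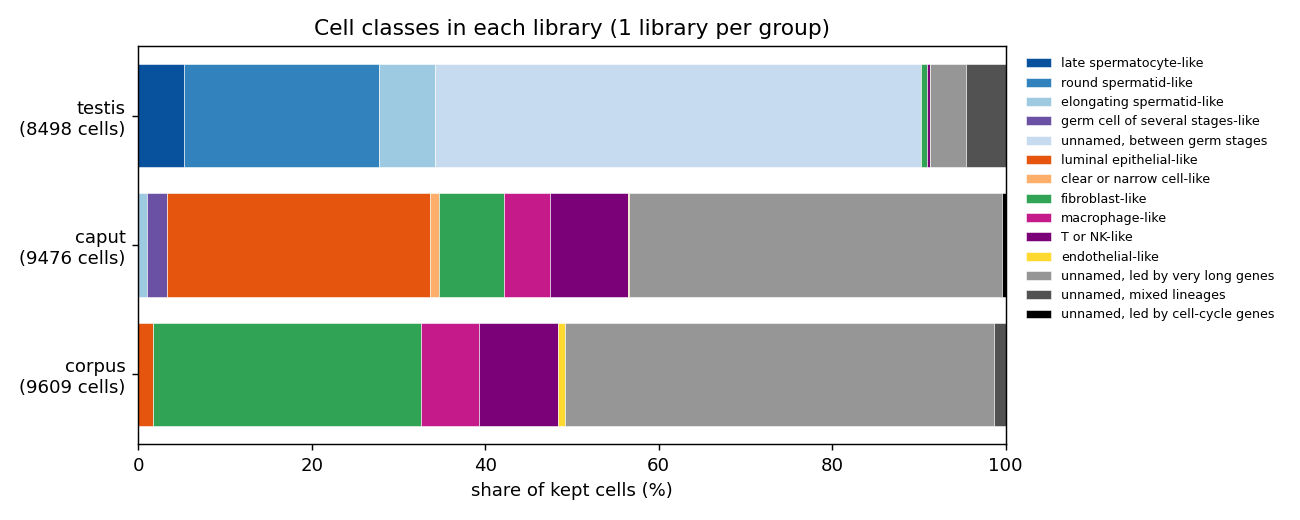
Horizontal bars give each class as a share of kept cells (%), 1 bar per library. The testis bar is mostly germ-like, while unnamed clusters led by very long genes take 43.0% of caput and 49.5% of corpus.

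Caput and corpus were compared because sperm mature as they pass from one to the other. In luminal epithelial-like cells, caput clusters 2, 5 and 6 together (2875 cells, 4082307 UMIs) were set against corpus cluster 6 (164 cells, 127683 UMIs). Caput cells carried DEFB119, a beta-defensin, at 14098 CPM against 0 UMIs in corpus, at least 600.0-fold higher. EDDM13, an epididymal secretory protein (5686 CPM, at least 242-fold), the secreted ribonuclease-family protein RNASE10 (3955, at least 168-fold), and the lipocalins LCN6 (2179.9, at least 92.8-fold) and LCN10 (706, at least 30.05-fold) had 0 UMIs in corpus too. Corpus cells carried CD52, a glycoprotein passed to the sperm surface, at 15131 CPM against 39.9 in caput (379-fold, 323 to 447). They carried LTF, the iron-binding lactotransferrin, at 7558 against 156 CPM (48.5-fold, 43.8 to 53.7), and PATE1, a sperm-associated protein, at 5803 against 2.45 CPM (2369-fold, 1281 to 4961).

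By the size rule, 50 genes were higher in caput (35 with a symbol) and 45 in corpus (39 with a symbol) of 7197 genes with at least 50 UMIs on the higher side. Caput genes also included DEFB113 (2358 CPM, at least 100.4-fold), the cystatin CST11 (1280.4, at least 54.5-fold), DEFB128 (690.5, at least 29.4-fold) and DEFB127 (424.5, at least 18.1-fold). The reticulum protein RCN1 (1716 CPM, 219-fold, 39.3 to 8656) and DEFB121 (1560.4 CPM, 199-fold, 35.7 to 7871) each had 1 UMI in corpus. PTGDS, a prostaglandin D synthase, stood at 1692 against 47.0 CPM (36.0-fold, 16.5 to 98.2). Corpus genes also included the protease inhibitor SPINT4 (1472 CPM against 0 UMIs, at least 2004-fold), LY6L (1136 against 0.980, 1159-fold, 443 to 4311), DEFB126 (1441 against 1.47, 980.5-fold, 442 to 2706) and DEFB125 (1308 against 1.71, 763-fold, 362 to 1926). They further included WFDC13 (272-fold, 149 to 543), the carboxylesterase CES5A (166-fold, 114 to 247), DEFB136 (155-fold, 128 to 189), DEFB115 (45.8-fold, 32.6 to 64.8) and RNASE11 (37.2-fold, 26.1 to 53.3).

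The class was compared by cluster number as well, since DEFB119, which leads caput cluster 2, is also in the fixed Sertoli list. Against corpus cluster 6, caput cluster 2 had 33 genes higher and 54 lower, cluster 5 had 37 and 32, and cluster 6 had 62 and 49, with 23 and 31 genes shared by these comparisons. The 12 named corpus genes stood beyond 4-fold against every caput cluster, and so did 8 of the 12 named caput genes. The exceptions were CST11, DEFB128, PTGDS and DEFB127, which were concentrated in caput cluster 6: CST11 had 4877 CPM there against 56.3 in cluster 2 and 46.4 in cluster 5, and PTGDS 6145 against 215 and 102. Several of these genes also lead a cluster, DEFB119, EDDM13 and LCN10 in caput cluster 2, CST11, LCN6, PTGDS and DEFB127 in caput cluster 6, and LTF, PATE1, DEFB136 and CD52 in corpus cluster 6. CD52 and CES5A were naming markers. The 12 named caput genes were also seen in other caput classes, where they stood at a median of 14.5% of their luminal level in fibroblast-like, 11.97% in macrophage-like and 11.9% in T or NK-like cells. Free RNA and doublets were not separated as sources of this level. Of the corpus genes, CD52 (64.1 CPM), PATE1 (3.84) and CES5A (16.7) stood as high or higher in caput macrophage-like cells as in caput luminal cells (39.9, 2.45 and 8.33), so their folds are set against a level whose source was not tested. In corpus, 1 UMI equals 7.83 CPM and 50 UMIs equal 392 CPM, against 12.2 CPM for 50 UMIs in caput. Beta-defensins and lipocalins are multigene families, and how shared reads were counted is not given in the sources used here.

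**Figure D2:**
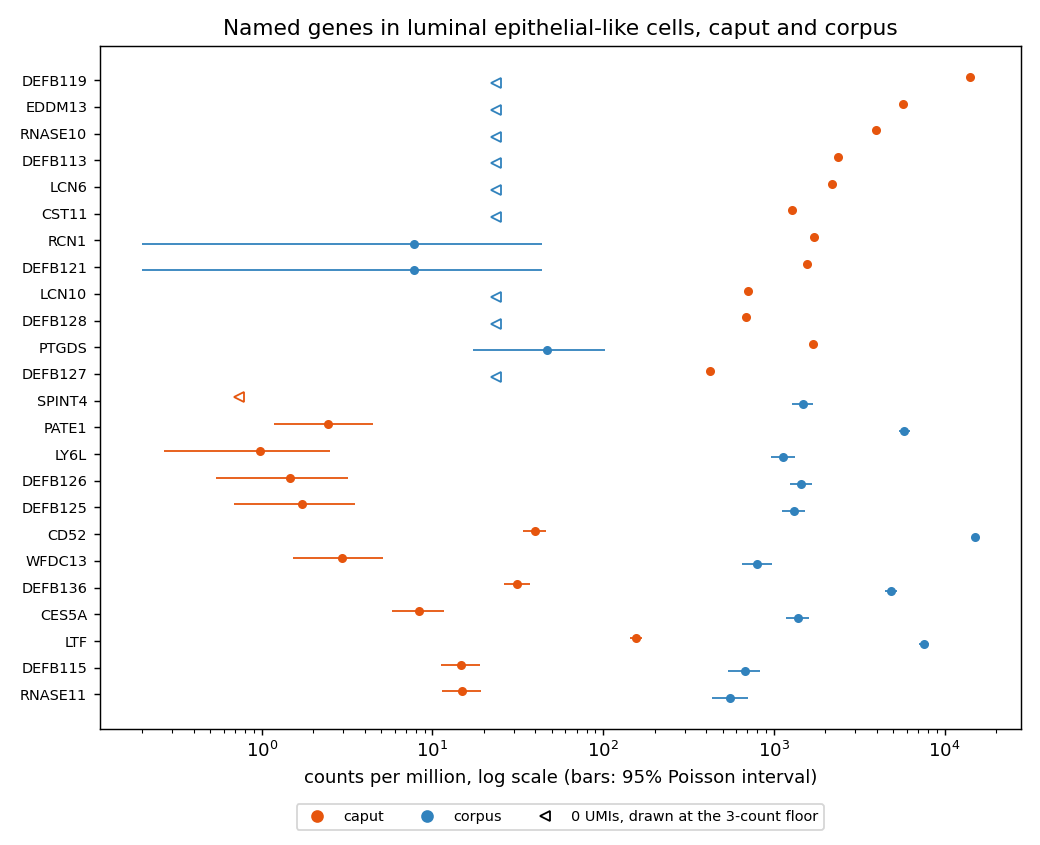
Points give CPM (log scale) of the 24 named genes in luminal epithelial-like cells of caput and corpus, bars the 95% Poisson interval, and open triangles 0 UMIs drawn at the 3-count floor. DEFB119 lies at 14098 in caput and at the floor in corpus, and CD52 at 39.9 in caput and 15131 in corpus.

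The fixed gene lists split between the luminal cells in different ways. Of 19 antimicrobial genes with enough UMIs, 9 were beyond 2-fold higher in caput and 9 in corpus, with 1 in neither group (median log2 ratio of caput over corpus 1.22, percentile 99.99 of random lists). As a share of UMIs the list did not lean to caput in every cluster, with 2.55% in corpus against 1.93%, 1.98% and 2.86% in caput clusters 2, 5 and 6. Of 29 lipocalins, cystatins, ribonucleases and proteases, 10 were higher in caput, 7 in corpus and 12 in neither (median -0.45, percentile 1.86). Sperm-coating and maturation genes leaned to corpus, with 7 higher there, 3 higher in caput and 4 in neither (median -1.97, percentile 0). Immediate-early and dissociation stress genes were also higher in corpus, 3 of 8 with 0 in caput (median -2.02, percentile 0): FOS stood at 556 against 42.1 CPM, JUN at 533 against 48.5 and the small heat shock protein HSPB1 at 3368 against 1480.

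Genes of the epithelial barrier and of transport gave few calls. Of 7 tight junction genes, CLDN8 (744 against 117 CPM) was higher in corpus and CLDN2 (60.3 CPM against 0 UMIs) in caput. ATP6V1C2, a proton pump subunit (587 against 37.5), was the 1 of 12 acidification genes higher in corpus. Of 15 antioxidant genes, 3 were higher in caput, among them the peroxidases GPX6 (166 CPM against 0 UMIs) and PRDX6 (680 against 204), and 0 in corpus. PDIA6, a protein folding enzyme (916 against 309), was the 1 of 12 reticulum genes higher in corpus, and CD74 (666 against 164) the 1 of 2 genes of MHC class II presentation. The 1 of 13 matrix genes past the rule was DCN (1316 against 172), which is not taken as expressed by luminal cells, since this fibroblast gene stood at 1628 CPM in corpus T or NK-like cells too. Of 38 X-linked genes, 2 were higher in caput and 4 in corpus, LAMP2 among the latter (3744 against 647 CPM).

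No member passed the 2-fold rule among 51 ribosomal protein genes (median 0.40), 34 genes of oxidative phosphorylation (0.13), 11 smooth muscle genes, 9 genes each of hormone receptors, steroidogenesis, germ-cell glycolysis and the interferon response, 7 patterning transcription factors, 5 retinoic acid genes and 3 chemokines. The same held for the lists of meiosis (13 genes), piRNA (7), transition proteins (5), acrosome (7), flagellum (21), cell cycle (9) and autosomal counterparts of X-linked genes (1). A gene with 0 UMIs in corpus has an upper limit of 28.9 CPM there, while 50 UMIs in caput equal 12.2 CPM. Members at low levels in caput, here and in the lists above, therefore could not pass upward. For them the absence of a call is not a result. Thinning the caput sums to the corpus total, an alternative chosen after seeing the data, left 28 genes higher in caput and 40 in corpus, so that caput held 41.2% of the calls in place of 52.6%. With at least 50 UMIs on either side, another such alternative, 76 genes were higher in corpus and the caput share was 39.7%. A planned minimum of 10 UMIs gave 107 and 31.8%, so which side held more of the calls depended on these choices.

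Whole libraries were also compared, which needs no clusters or names. Here 403 genes were higher in caput (265 with a symbol) and 49 in corpus (39 with a symbol), of 17768 with at least 50 UMIs on the higher side. Caput was led by DEFB119 (5748 against 3.38 CPM, 1700.5-fold, 1013 to 3111), DEFB113 (911 against 1.45), LCN6 (776 against 1.45), LCN10 (278 against 0.483) and RNASE10 (1428 against 6.28), followed by DEFB128, EDDM13, CST11 and DEFB121. The remaining named caput genes were germ-cell genes: PPP3R2, a testis calcineurin subunit (123 against 0.483 CPM, 254-fold, 70.3 to 2103), the centrin CETN1 (98.7 against 0.483, 204-fold, 56.5 to 1689) and the transition protein gene TNP1 (152 against 1.21, 126-fold, 54.0 to 389). Corpus was led by SPINT4 (50.2 against 0.455 CPM, 110.4-fold, 49.9 to 304), PATE1, LY6L, DEFB126, CD52, DEFB125 and DEFB136, and by genes of the stroma and of macrophages. The matrix proteoglycan DCN stood at 13856 against 1562 CPM (8.87-fold, 8.73 to 9.01), the apolipoproteins APOE at 8268 against 823 (10.1-fold) and APOD at 6355 against 626 (10.2-fold), the enkephalin precursor PENK at 167 against 10.1 (16.6-fold) and S100A4, mostly of macrophage-like cells (188 of 302 UMIs), at 72.9 against 8.11 (8.99-fold).

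By list, 21 of 42 matrix genes were higher in corpus and 0 in caput (median -1.46, percentile 0), among them MFAP5 (117 against 19.6 CPM), TIMP3 (869 against 206) and FBLN1 (842 against 201). Immediate-early genes went the same way, 14 of 32 against 1 (IER3, NR4A2, SOCS3 and ATF3 lead), as did 4 of 15 chemokines (CXCL12 442 against 66.9, CFD 94.9 against 12.7). In caput, 26 of 52 ribosomal protein genes (median 1.11), 20 of 47 oxidative phosphorylation genes (1.28, UQCRQ 165 against 36.0) and 10 of 31 reticulum genes (1.04, SEC61B 296 against 44.9) were higher, with 0 higher in corpus. Germ-cell lists were higher in caput alone as well, with 9 of 11 transition protein genes, 8 of 21 acrosome, 11 of 42 flagellum and 8 of 17 germ-cell glycolysis genes. The epididymal lists gave 10 antimicrobial genes higher in caput and 6 in corpus, 19 and 4 lipocalins and their group, and 8 and 4 sperm-coating genes. These sums mix composition and expression. A minimum of 500 genes per cell, which kept 10.5% of corpus barcodes, left 150.0 genes higher in caput and 67 in corpus (69.1% of the calls in caput in place of 89.2%). Without germ-like clusters the counts were 231 and 42, and without clusters led by very long genes 420 and 94, both chosen after seeing the data.

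In the other classes found in both regions, the genes higher in caput were mostly genes of luminal cells. Fibroblast-like cells had 55 genes higher in caput and 2 in corpus, macrophage-like cells 47 and 10, and T or NK-like cells 59 and 9. A minimum of 10 UMIs gave 85 fibroblast genes higher in caput and 17 macrophage and 18 T or NK genes higher in corpus, and clustering the libraries together gave 5 for the last. Most of the named caput genes were secretory. DEFB119 reached 2576 CPM in caput fibroblast-like cells (2.24 in corpus), 2582 in macrophage-like cells (3.01) and 3184 in T or NK-like cells (0 UMIs). BSPH1, a sperm-binding protein, reached 2704, 3068 and 3515 (17.2, 27.1 and 42.7 in corpus). EDDM13, DEFB113, LCN6, MUC15, CITED1 and RNASE10 completed these lists. Of the genes higher in caput, 54 of 55, 44 of 47 and 56 of 59 stood at least 3-fold higher in another abundant class of the caput library. The few that did not, named after their values were seen, were EPYC, a cartilage-type proteoglycan (98.7 against 14.2 CPM, 6.97-fold, 4.25 to 12.03), in fibroblast-like cells, HOPX (573 against 48.4, 11.8-fold, 7.34 to 20.5), PFN2 (117 CPM against 0 UMIs, at least 13.7-fold) and LAMTOR2 (67.2 against 2.85, 23.6-fold, 4.12 to 944) in T or NK-like cells, and 3 genes without a symbol in macrophage-like cells. Another abundant caput class carried more of HOPX and PFN2 (1632 and 346 CPM), close to that limit, and of LAMTOR2 (139).

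On the corpus side, macrophage-like cells had higher NR4A3 (427 against 33.3 CPM, 12.8-fold, 8.39 to 20.3) and NR4A2 (989 against 101, 9.77-fold, 7.62 to 12.7), nuclear receptors of the immediate response. They also had higher FOSL2 (247 against 23.1, 10.7-fold, 6.36 to 18.9), S100A4 (565 against 55.1, 10.3-fold, 7.33 to 14.6) and CFP, properdin of the complement system (180.4 against 16.7, 10.8-fold, 5.88 to 21.5). None of these 10 genes stood 3-fold higher in luminal or fibroblast-like cells of corpus. Immediate-early genes as a list were higher in corpus macrophage-like cells for 8 of 23 members and in T or NK-like cells for 2 of 22, with 0 higher in caput (medians -0.98 and -0.65). In fibroblast-like cells 5 of 23 were higher in corpus. As this list had members higher in corpus in every class compared, handling of the tissue is not set apart from region here. ATF3 led the fibroblast members (150.0 against 17.9 CPM, 8.39-fold, 5.24 to 14.2). CD52 (88.0 against 9.40) was the other listed fibroblast gene, and its level in corpus fibroblast-like cells was 0.582% of that in luminal cells. PENK (454 against 103, 4.39-fold, 3.58 to 5.43), APOD (17532 against 6670, 2.63-fold) and FOS (1563 against 562, 2.78-fold) did not reach the 4-fold rule there. In T or NK-like cells the named corpus genes APOE, APOD, DCN, COL1A1 and COL1A2 (5.72-fold to 14.0-fold) are fibroblast genes, at least 3-fold higher in corpus fibroblast-like cells.

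Stages of sperm formation were followed through 10 of the 11 testis germ-like clusters (without the mixed cluster 13), ordered by the ratio of spermatid to spermatocyte markers from position 1 (449 late spermatocyte-like cells) to position 10 (186 elongating spermatid-like cells). Transition protein and protamine genes, which repackage sperm DNA, took 0.144% of UMIs at position 1, 1.015% at position 9 and 5.35% at position 10. TNP1 stood at 60.9 CPM (53.1 to 69.5) at position 1 and at 24548 (24216 to 24884) at position 10, PRM2 at 27.6 and 12492, and HMGB4 at 55.4 and 6655; these markers also set the order, and without stage markers the list took 0.126% and 0.280%. Flagellum genes went from 1.23% to 2.27%, with ODF2, of the outer dense fibres, at 1437 and 4200.3 CPM and the calcium-binding sheath protein CABYR at 2252 and 3181. Some flagellum genes, such as AKAP4 and ODF1, are also markers that set the order. Acrosome genes reached 0.898% at position 9, against 0.606% at position 1 and 0.569% at position 10. Among their most abundant members, IZUMO4 stood at 1676 CPM at position 1 and 319 at position 10, and ACRBP at 1238 and 375.

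Cell-cycle genes ran the other way, with 0.789% of UMIs at position 2 and 0.0845% at position 10 (0.658% and 0.0697% without stage markers), and with the mitotic kinase AURKA, itself a marker that set the order, at 942 CPM (911 to 974) and 65.0 (49.0 to 84.6) at the ends of the order, and PLK1 highest at position 4 (839). Synaptonemal complex and recombination genes went from 0.471% to 0.182%, SYCP2 from 726 to 79.2 CPM and SYCP1 from 406 to 61.4, but most of that share is of stage markers, and the other members took 0.0747% and 0.0242%. The piRNA genes went from 0.444% to 0.208%, TDRD6 from 798 to 108 CPM, but GTSF1 was highest at position 9 (743 against 244 at position 1). Glycolysis genes of the germ line dipped to 0.332% at position 4 and stood at 0.549% at position 10, reticulum folding genes went from 0.981% at position 5 to 0.343%, and oxidative phosphorylation genes from 1.08% to 0.549%. Ribosomal protein genes took 2.09% and 1.76% at the ends of the order. HSP90AA1, a chaperone of the stress list, stood at 4480.3 and 526 CPM. GPX4, the selenoenzyme of the sperm midpiece, stood at 746 and 1336 CPM.

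Between late spermatocyte-like and round spermatid-like cells, 7 of 12 transition protein genes passed 2-fold upward and 0 downward (median log2 ratio 3.55, 0.33 without stage markers), 12 and 1 of 22 acrosome genes (1.95, 1.23 without markers) and 16 and 6 of 47 flagellum genes (0.26). Cell-cycle genes passed 2-fold upward in 3 and downward in 13 of 26 (median -1.44, percentile 0), and piRNA genes in 1 and 9 of 18 (-0.57). Between round and elongating spermatid-like cells, 8 of 12 transition protein genes passed upward (1.63, 0.89 without markers), cell-cycle genes passed downward in 4 of 25 (-0.75), and the median of reticulum genes (-0.49) lay at percentile 0.86. Flagellum genes did not rise as a list in this second step, with 4 of 47 upward and 2 downward (median -0.24, -0.30 without markers). Synaptonemal genes passed upward in 5 and downward in 5 of 23 in the first step (median -0.15, 0.16 without markers), and had medians of -0.61 (percentile 0.67) and, without markers, -0.32 (percentile 31.3, 4 members) in the second. The median of all genes was -0.18 and -0.15 in these steps. In testis fibroblast-like cells TNP1 had 302 CPM and PRM2 188, and free RNA and doublets were not separated as sources.

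**Figure D3:**
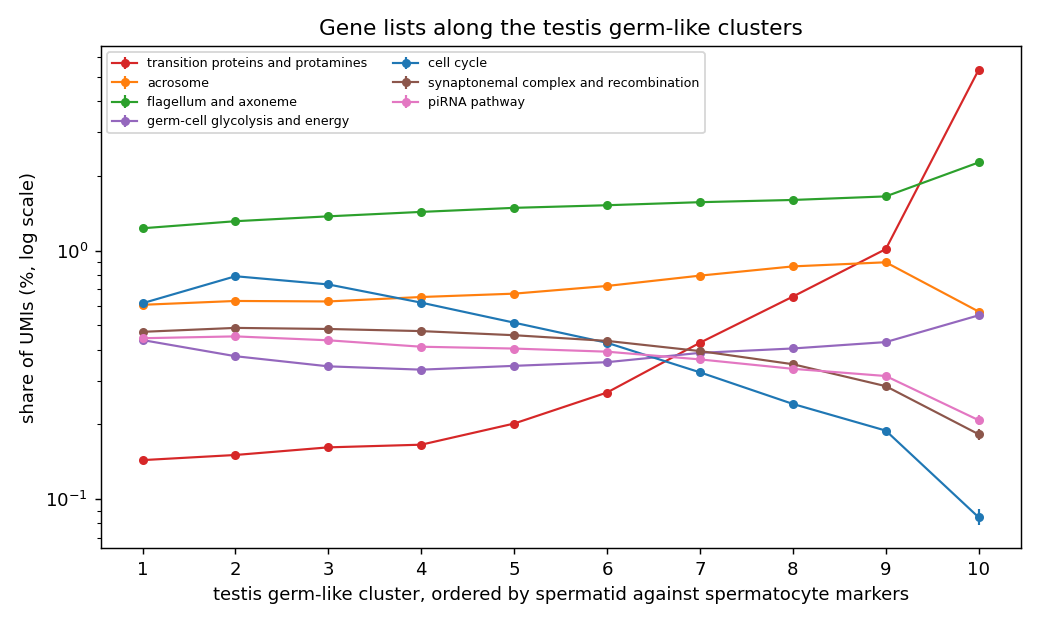
Lines give the share of UMIs (%, log scale) of 7 gene lists in 10 testis germ-like clusters ordered by spermatid against spermatocyte markers, with 95% intervals mostly hidden by the points. At position 10 transition protein genes stand at 5.35% and cell-cycle genes at 0.0845%.

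Genes on the X chromosome, which is silenced in meiosis in males, were followed along the same order. The 88 X-linked genes took 0.0246% of UMIs in late spermatocyte-like cells (0.0231 to 0.0263%), 0.217% in round spermatid-like and 0.209% in elongating spermatid-like cells. Testis fibroblast-like cells had 1.13% (1.07 to 1.19%), 45.9-fold (42.2 to 49.99) above late spermatocyte-like cells and 7.31-fold (6.92 to 7.71) above all germ-like cells, and T or NK-like cells had 1.41%. Without ribosomal protein genes these ratios were 32.2-fold (29.2 to 35.5) and 4.70-fold (4.39 to 5.03), and the share in T or NK-like cells was 0.585%, below the 0.700% of fibroblast-like cells. Both terms of the first ratio depend on the processing, the fibroblast-like share being 0.455% with doublets kept and the late spermatocyte-like share 0.0583% with the libraries clustered together. From position 1 to position 7 the share went from 0.0246% to 0.219%, and it stayed between 0.206% and 0.216% after that. Of 35 X-linked genes with at least 50 UMIs on the higher side, 29 passed 2-fold upward from late spermatocyte-like to round spermatid-like cells and 0 downward.

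Single X-linked genes differed in their course. UPF3B, of nonsense-mediated decay, stood at 16.3 CPM (12.4 to 21.0) at position 1, 522 (505 to 539.7) at position 7 and 155 at position 10, and MORF4L2 at 17.9, then 165 at position 6 and 41.4. CETN2 (24.3 and 349 CPM) and SYAP1 (10.5 and 211) were highest at position 10. The translation factor EIF1AX was at 4.87 CPM or less up to position 9 and at 135 (111 to 162) at position 10, FUNDC2 went from 2.48 to 198 and the helicase DDX3X from 4.41 to 161. The ribosomal genes RPL10 and RPS4X stayed at 39.0 CPM or less and 43.0 or less in every position, against 1888 and 1438 in fibroblast-like cells. Autosomal counterparts of X-linked genes took 0.416% at position 1 and 0.169% at position 10, with CETN1 at 2561 and 451 CPM and PGK2, the germ-line phosphoglycerate kinase, at 809 and 566. No comparison with spermatogonia was possible, because no cluster was named for them.

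**Figure D4:**
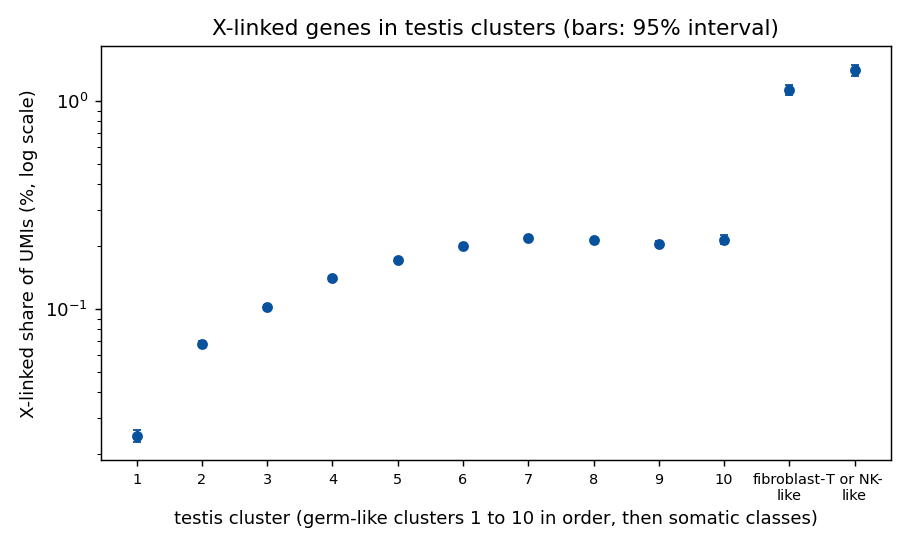
Points give the share of UMIs (%, log scale) from 88 X-linked genes in 10 ordered germ-like clusters and in fibroblast-like and T or NK-like cells of testis, with 95% intervals. The share goes from 0.0246% at position 1 to 0.219% at position 7, and lies at 1.13% and 1.41% in the somatic classes.

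Germ-cell transcripts were also sought in the epididymal libraries. The 36 spermatid markers took 0.781% of UMIs in testis (0.779 to 0.784%), 0.0997% in caput (0.0980 to 0.101%) and 0.0265% in corpus (0.0249 to 0.0281%). In caput they were concentrated in cluster 9 (96 cells, 3.85%), with AKAP4, a protein of the sperm tail, at 2205 CPM, ODF1 at 2150.0, TNP1 at 11320.2 and PRM2 at 5997. In testis position 10 the same genes stood at 1700.2, 2791, 24548 and 12492 CPM. Caput cluster 8 (217 cells, 0.351%) carried CETN1 at 1374, PPP3R2 at 1717 and the chaperone CLGN at 3673 CPM. Across genes, which are not independent replicates, the profile of cluster 8 had its highest Pearson correlation with testis position 4 (r = 0.721, and 0.718 with position 3). By rank (Spearman) position 3 was highest (0.767, and 0.759 with position 4). Cluster 9 correlated above 0 with position 10 alone among the germ positions (r = 0.128). Some of these genes lead or name their clusters. Other caput classes held the markers at lower shares, 0.0325% in luminal, 0.0326% in T or NK-like, 0.0319% in clear or narrow cell-like, 0.0302% in fibroblast-like and 0.0290% in macrophage-like cells, with 0.00747% (0.00154 to 0.0218%) in endothelial-like cells and 0.0544% (0.0524 to 0.0565%) in the clusters led by very long genes. In corpus no cluster was germ-like, which sets no limit on single germ cells at its depth, and the 18 elongating spermatid markers took 0.00270%. Of the 1097 corpus UMIs of the 36 markers, 713 lay in clusters led by very long genes (0.0378%, 0.0351 to 0.0407%). Named corpus classes ranged from 0.0110% in luminal to 0.0211% in T or NK-like cells. Whether these corpus UMIs are of germ cells was not tested.

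Fibroblast-like cells were the one somatic class with at least 50 cells in testis and epididymis. Testis fibroblast-like cells (55 cells, 122359 UMIs) were higher than those of both epididymal regions in LHX9, a gonadal transcription factor (817 CPM against 12.2 in caput, 66.8-fold, 37.4 to 129.9, and 14.2 in corpus, 57.7-fold, 35.1 to 99.8). The same held for smooth muscle actin ACTA2 (2182 against 45.1 and 57.4 CPM, 48.3-fold and 38.0-fold) and STMN2 (703 against 20.7 and 13.4, 34.0-fold and 52.3-fold). CFD, complement factor D, was 18.0-fold (14.7 to 22.2) and ADIRF 19.7-fold (13.3 to 29.9) above caput. ACTA2, DCN, APOD and APOE also lead the testis cluster. ACTA2 is a fixed marker of smooth muscle or peritubular myoid cells, for which no testis cluster was named. Whether these 55 cells include other cell types was not tested, so a difference in cell type is not set apart from one in tissue. The opiate precursor gene PENK was 55.6-fold higher in corpus (454 against 8.17 CPM, 9.94 to 2199, 1 UMI in testis), as were NCAM1 (41.4-fold, 7.40 to 1640.5) and MYO5B (24.8-fold, 6.83 to 205), while CDH13 (at least 10.7-fold) and PTPRN2 (at least 9.34-fold) had 0 UMIs in testis. CDH13 is among the very long genes, whose list took 0.415% of UMIs in testis fibroblast-like cells against 1.84% in those of caput and 1.76% and 3.14% in the corpus clusters.

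Against caput 32 genes were higher in testis and 62 in caput, and against corpus 36 and 44. With TMM factors these became 28 and 89, and 31 and 90, so that the testis share of the calls was 23.9% in place of 34.0% against caput, and 25.6% in place of 45.0% against corpus. A minimum of 10 UMIs moved the balance the other way, with 107 and 160.0 genes higher in testis (63.3% and 78.4% of the calls). The named caput genes BSPH1, DEFB119, EDDM13, CLU and RNASE9 (0 UMIs in testis, at least 24.97-fold to 110.3-fold) are genes of caput luminal cells. GSTM3 (2558 against 23.1 CPM) and SPA17 (1193 against 18.7), named against corpus, stood at higher levels in testis germ cells. Without genes at least 3-fold higher in an abundant class of the same library the counts were 22 and 28 against caput and 23 and 43 against corpus. By list, smooth muscle genes were higher in testis for 5 of 11 members against caput (MYLK 678 against 105 CPM) and 5 of 11 against corpus (TPM1 580 against 110.4), with 2 lower each time (PRKG1 and RYR2). Matrix genes were lower in testis for 9 of 28 and 6 of 25, with 2 higher each time (COL1A1 654 against 4225 in caput and 3360.2 in corpus). Immediate-early genes were higher in testis for 4 of 10 and 2 of 13, CCN2 in front (1144 against 108 and 76.1 CPM), and of the hormone receptors 1 of 13 and 2 of 14 were lower.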

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

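All tests of explanations in this part were chosen after the results were seen. Germ-like clusters held 3.30% of caput cells (2.95 to 3.68%, 313 of 9476), in a library whose label names somatic cells; they stand here because they are a signal outside the comparisons, above the 0.0317% that a count of 0 allows. Free RNA of germ cells spread evenly is argued against for the caput cells with at least 20 UMIs of spermatid markers only. There were 94 such cells, while even spreading at each cell's depth gave 2.48 cells on average and 6 at most in 200 draws. Of the 94, 93 lay in germ-like clusters, but these markers also name clusters. Germ-like cells with fewer such UMIs are not covered. The minimum of 20 UMIs was added after a minimum of 5 did not separate the numbers (250 cells against 285 drawn on average). The testis suspension mixed in cannot be told apart. At 1000 UMIs per cell, elongating markers led in 24.7% of germ marker-bearing caput cells (19.96 to 29.9%, 76 of 308) and in 5.09% of those of testis (4.63 to 5.59%, 428 of 8401). Cells below 1000 UMIs were left out on both sides. The testis file starts at 1816 UMIs, above the median of 1425 of the caput germ-like cells. Cells between 1000 and 1816 UMIs are therefore missing from the testis side alone. Germ cells shed into the duct lumen may be another source, but this cannot be told apart either, since at 290 UMIs per cell there was 1 such cell in corpus and 62 in caput, with 1 library per region.

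Clusters led by very long genes held 4.14% of testis cells (3.73 to 4.59%), 43.0% of caput cells (42.0 to 44.0%) and 49.5% of corpus cells (48.5 to 50.5%). They stand here as signals that no comparison between cell classes used, above the limits of a 0 count (0.0353%, 0.0317% and 0.0312%). Nuclei or cells without cytoplasm may be a source, as ribosomal protein genes took 1.45% of UMIs there against 6.70% in the other caput clusters, and 0.303% against 4.13% in corpus. The caput value joins unlike clusters, with 0.831% in cluster 0 and 2.59% in cluster 1. The latter lies near the 2.78% of germ-like cluster 8, the lowest of the other caput clusters. In testis the shares were close, 1.51% against 1.83%, but this comparison cannot decide there. Testis germ-like clusters, which make up most of the latter, themselves had low shares (1.55% to 2.09%). The testis fibroblast-like and T or NK-like clusters had 5.62% and 15.98%. Droplets with free RNA alone cannot be told apart, because doublets remain in the classes set beside these clusters and may raise their levels. In caput cluster 0 DEFB119 stood at 796 CPM (766 to 828). The lowest class that should lack it, endothelial-like cells (19 cells), had 1195 (881 to 1584). In corpus cluster 0 DCN stood at 888 CPM (840.0 to 937) against 1316 (1124 to 1530.4) in the lowest such class. Free RNA alone would put both clusters above such classes unless doublets raised the levels in these classes enough. Caput cluster 1 had DEFB119 at 2725 CPM, between the classes that should lack it, and corpus cluster 2 had DCN at 1085 CPM (988 to 1189). Shallow cells cannot be told apart either: the median UMIs were 0.886 of those of other clusters in caput and 0.887 in corpus, but the floor of UMIs in the files keeps these ratios above 0.696 and 0.747. A biological explanation was not tested.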

How the results depend on the processing

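Alternatives on thinning, caput cluster 2, the 5% highest doublet scores, very long genes, germ-like clusters, free RNA, 50 UMIs on either side and X-linked shares were chosen after the results were seen. Of 175 values, 124 were counted as the same and 51 as moved. A share counted as the same inside the 95% interval of its main value. A number of listed genes counted as the same within a fixed fold of its main value, so it could still change. Keeping doublets could return only 2 barcodes in caput and 0 in corpus. The number 124 is therefore not a measure of how stable the results are. Unless stated, the cause of a move was not tested. Totals without the 20 most abundant genes and means over cells moved none of the values they were run on. A minimum of 500 genes kept 99.9% of caput and 10.5% of corpus barcodes, which follows from the depth of corpus. It left a corpus median of 760.0 UMIs, corpus germ transcripts of 0.0204%, luminal shares of 29.1% in caput and 7.25% in corpus, and 150.0 genes higher in whole caput, 69.1% of the listed genes in place of 89.2%. Keeping doublets kept 100% of testis and of caput barcodes by construction, with testis germ transcripts of 0.778%, caput luminal cells at 28.8%, germ-like cells at 90.9%, spermatids at 35.0% of them and an X-linked share of 0.455% in testis fibroblast-like cells; no late spermatocyte-like class of at least 20 cells was then found. Removing the 5% highest doublet scores gave 1.09% luminal cells in corpus and an X-linked share of 0.153% in germ-like cells. Leiden resolution 0.5 gave caput luminal cells 32.0% and germ-like cells 92.7%. Resolution 2.0 gave caput luminal cells 20.4% and spermatids 40.9%, and the larger set of variable genes 23.4% and 47.9%. Clustering the libraries together gave caput luminal cells 38.2%, germ-like cells 98.5%, spermatids 0%, X-linked shares of 0.159% in germ-like and 0.0583% in late spermatocyte-like cells, and 5 genes higher in corpus T or NK-like cells. A minimum of 10 UMIs, which tests more genes, listed 107 luminal genes higher in corpus (31.8% of the listed genes higher in caput, in place of 52.6%). It also listed 85 fibroblast genes higher in caput, 17 macrophage and 18 T or NK genes higher in corpus, and 107 and 160.0 testis fibroblast genes higher than in caput and corpus; the splits of the last 3 were 76.6% for 86.8%, 63.3% for 34.0% and 78.4% for 45.0%. A minimum of 50 UMIs on either side, which admits corpus genes with few UMIs, gave 76 luminal genes higher in corpus (39.7% higher in caput). The side with more listed genes reversed with 10 UMIs in the luminal and both testis comparisons, and in the luminal one also with 50 UMIs on either side, with thinned caput sums and, at 49.5%, with the libraries clustered together. TMM factors gave 90.0 fibroblast genes higher in corpus than in testis (25.6% for 45.0%). Thinning caput to the corpus total, which lowers counts, gave 28 luminal genes higher in caput (41.2%). Outside clusters led by very long genes, luminal shares were 53.2% and 3.38%, and whole corpus had 94 higher genes; without germ-like clusters whole caput had 231. Without ribosomal protein genes the X-linked shares were 0.149% in germ-like, 0.0217% in late spermatocyte-like and 0.700% in fibroblast-like cells, by construction. Without genes 3-fold higher in another abundant class, also by construction, fibroblast-like cells had 1 gene higher in caput and 1 in corpus, macrophage-like cells 3 in caput, T or NK-like cells 3 and 3, caput fibroblasts 28 against testis, and testis fibroblasts 23 against corpus. The mitochondrial maximum was not run, as no such gene was listed, and the planned X-linked comparison with spermatogonia gave no value, as no such cluster was named. No paired analysis was possible because no label ties libraries to an animal.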

Other observations

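The tests of explanations in this part, and the choice of the genes of clear or narrow cell-like cells, came after the values were seen. Clear or narrow cell-like cells of caput (96 cells, 131786 UMIs), which acidify the lumen, carried transport genes at levels unlike those of the luminal epithelial-like clusters. Acidification genes took 0.914% of their UMIs (0.864 to 0.967%), against 0.228%, 0.236% and 0.204% in caput luminal clusters 2, 5 and 6 and 0.276% (0.248 to 0.306%) in corpus luminal cells. Channel and carrier genes took 0.319% (0.290 to 0.351%) against 0.0570%, 0.0634% and 0.0723%, and 0.131% in corpus luminal cells, and oxidative phosphorylation genes 1.64% (1.57 to 1.71%) against 0.824%, 0.887% and 0.846%. The proton pump subunit ATP6V1C2 stood at 683 CPM (549 to 839) in these cells and at 587 (462 to 736) in corpus luminal cells. Lipocalins and their group took 0.923% in clear or narrow cell-like cells and 2.47%, 4.33% and 6.46% in the caput luminal clusters, and the 12 named luminal genes of caput stood in the former at a median of 6.67% of their luminal level. Immediate-early and dissociation stress genes were high in these cells too, at 0.981% of UMIs (0.929 to 1.036%) against 0.314%, 0.344% and 0.291% in the caput luminal clusters and 0.764% in corpus luminal cells, so that handling of the tissue is not set apart from cell type here. Several pump genes lead or name this cluster.

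Hormone receptor and steroid enzyme genes were low in testis germ-like cells, with some exceptions. ESR1, an estrogen receptor, stood at 5.51 CPM (3.37 to 8.51) at position 1 and 113 (103 to 124) at position 8, and SRD5A3, a reductase of the steroid family, at 13.2 (9.75 to 17.5) and, at position 9, 162 (147 to 179). CYP19A1, which makes estrogen, was highest at position 1 (44.4 CPM, 37.8 to 51.8) and at 3.54 (0.731 to 10.4) at position 10. CYP11A1, which opens steroid synthesis, stood at 57.2 CPM (23.0 to 118) in fibroblast-like cells and at 0.905 or less in every germ position.

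Genes listed as higher in caput in fibroblast-like, macrophage-like and T or NK-like cells were weighed as a pattern. Free RNA of luminal epithelial cells may be the source, since 95.03% of the listings (153 of 161) were of genes at least 3-fold higher in caput luminal cells. A gene counts there in each class that lists it. Of the 38 genes listed in every class, 0 differed by more than 3-fold among these classes. A different scaling of the libraries is argued against, as the lowest number of listed genes with TMM factors was 1 times the number without them. Doublets, of which 2 were called in caput and 0 in corpus, stay open, and a biological explanation was not tested.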
